A study of Brassica rapa with 15 samples.

How the data were processed

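The series holds chromatin immunoprecipitation sequencing of the K2 line of Brassica rapa, with antibodies against trimethylated lysine 4 of histone H3 (H3K4me3) and against H3 itself. Its 15 libraries come from leaf, late unicellular microspores, microspores after heat shock and microspores without heat shock. H3 has 2 libraries in each of the 4 sources, H3K4me3 has 2 in each of the 3 microspore sources and 1 in leaf. The labels do not say whether replicates came from separate plants or cultures.

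The values analysed are 4 tracks, 1 per source, which the authors deposited as log2 fold enrichment of H3K4me3 over H3 in 50-bp windows, per the feature names inside the files. Per those names each microspore track pools 2 H3K4me3 libraries and the leaf track holds 1. Those names also hold the letters sub_FE, and whether H3 was subtracted, divided by or both is not given in the sources used here. The values were treated as log2 fold over H3, and every level and fold in the text rests on that reading. How the H3 libraries were combined is not given in the sources used here. Trim Galore, Bowtie2, SAMtools and MACS2 are named in the submitters' processing notes, without versions. Read length, filters, duplicate handling and the genome build are not given in the sources used here. Every listed value lies above 0, the lowest at 1.44e-05, so a window without enrichment over H3 is not listed and cannot be told from a window without reads. Levels are therefore means over listed windows, and the listed range truncates differences at weakly marked places.

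Replicates are pooled inside the tracks, so no spread between replicates, no test and no p-value could be computed, and every difference below compares tracks and has no replicate check. The labels' replicate numbers could not be used for the same reason. Depth was estimated from the median step between the 8 most common folds in windows with a single interval behind them. Such a step was taken as a single fragment. The interval number was taken from an attribute that the files do not define. By this estimate a fold of 2 rested on 3.8 fragments in late unicellular microspores, 4.1 in microspores without heat shock, 6.6 in microspores after heat shock and 9.7 in leaf. In late unicellular microspores 61.4% of those windows lay within 0.05 of a whole step, against 80.8% without heat shock, 84.5% after heat shock and 86.9% in leaf, so the late value is the least certain.

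The reference table at hand, of assembly CAAS_Brap_v3.01, is not of the build behind the tracks: listed windows on chromosome 9 reach 64.5 Mb, and its last gene on that chromosome ends at 45.2 Mb. No gene was assigned to any coordinate. The plan written before the data were examined had compared genes and 24 lists of genes by product name, and named a fallback for this case, regions and chromosomes in place of genes. The fallback was used, the gene lists were not tested, and the profile around gene starts became a profile around region midpoints. The leaf and tapetum marker lists meant to show other cell types were among those not tested. Coordinates are those of the tracks, counted from 1.

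Marked domains were runs of windows with log2 of 1 or more, with gaps of up to 100 bp joined, 200 bp or longer. Overlap of domains meant 1 bp or more. Domains of the 4 tracks were merged into 31619 regions. A region counted as marked in a track with 4 or more windows at log2 of 1 or more. For each pair of tracks the mean log2 value was taken over windows listed in both, 5 or more per region, and the difference was centred by subtracting its median over all regions compared. Levels given for the tracks of a comparison are over these shared windows, and levels of a further track beside them are over that track's own listed windows in the region. A region counted as higher or lower at a centred difference of 1, which is 2-fold. Named regions were the 10 highest and the 10 lowest centred differences per comparison among regions with 10 or more windows listed in both tracks. The condition that a named gene carry a product name could not apply. A bin of 1 Mb with at most 5 regions marked in all 4 tracks was called mark-poor.

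The comparison step was tested on simulated fragment counts with an assumed fragment length of 200 bp, fold 0.6 for unlisted windows and 200 regions with known differences per comparison. For microspores after against without heat shock, 100 regions were simulated at log2 1.5, of which 93 could be measured and 69 were called. Of 100 regions simulated at log2 2, 84 could be measured and 81 were called. Median estimated differences were 1.18 and 1.63, below the simulated log2 1.5 and 2, so differences were underestimated there. In this comparison 117 unchanged regions among 17850 regions were called too. The same simulation without any difference was run with fragments of 150, 200 and 300 bp. Only H3K4me3 fragments were drawn, so counting error of H3 and differences between libraries are left out of all simulations. Merging domains across tracks, the 600-bp length limit, the mark-poor bins and the assumed fragment lengths and fold were chosen after a first look at the values.

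Alternatives were no centring, quantile normalization, a lowess trend, unlisted windows at log2 of 0, other window minima and thresholds, odd or even windows, the median over windows, other domain settings and equal numbers of marked windows. Added after seeing the data were 500 bp to each side of region midpoints, regions outside mark-poor bins, and regions of 600 bp or longer. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.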

Results

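H3K4me3, a histone mark found mostly at the starts of transcribed genes, was measured relative to H3 in the inducible K2 line of Brassica rapa. The study asks how microspores, the immature pollen grains, are reprogrammed toward embryos by heat, a route called androgenesis. The design sets late unicellular microspores, the starting stage, beside microspores after heat shock and microspores without it, with leaf as a vegetative tissue. Listed windows numbered 508336 in late unicellular microspores, 466515 in microspores without heat shock, 460469 in microspores after heat shock and 487007 in leaf. Each source had a single track and hence no replicate spread, and levels are log2 fold over H3 as far as the tracks' own feature names tell.

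Each stage carried the mark in short, separate domains, and those of leaf were the longest. Late unicellular microspores had 21158 domains with a median length of 450 bp, microspores without heat shock 18778 with 550 bp, microspores after heat shock 17706 with 600 bp, and leaf 20740 with 800 bp. Domains covered 11.99 Mb in late unicellular microspores, 11.14 Mb without heat shock, 11.47 Mb after heat shock and 18.05 Mb in leaf. Domains of 2000 bp or longer numbered 472 in leaf, 2.28% of its domains, against 69, 45 and 68 in the late, no heat shock and heat shock tracks. The longest domain of leaf spanned 4500 bp, on chromosome 7 from 18610551 to 18615050, with a mean log2 fold of 2.39 over 90 windows. There the late track had 24 listed windows at 0.90, the track without heat shock 44 at 0.55 and the track after heat shock 18 at 0.47. The longest domain of late unicellular microspores, on chromosome 9 from 57369701 to 57373400, averaged 1.92 there, 1.80 without heat shock, 1.61 after heat shock and 2.35 in leaf. The leaf track also had the highest median level, 1.86 against 0.97, 0.98 and 1.01 in the late, no heat shock and heat shock tracks, and the most fragments behind a given fold, so lengths and counts at a fixed threshold are not matched for depth.

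**Figure D1:**
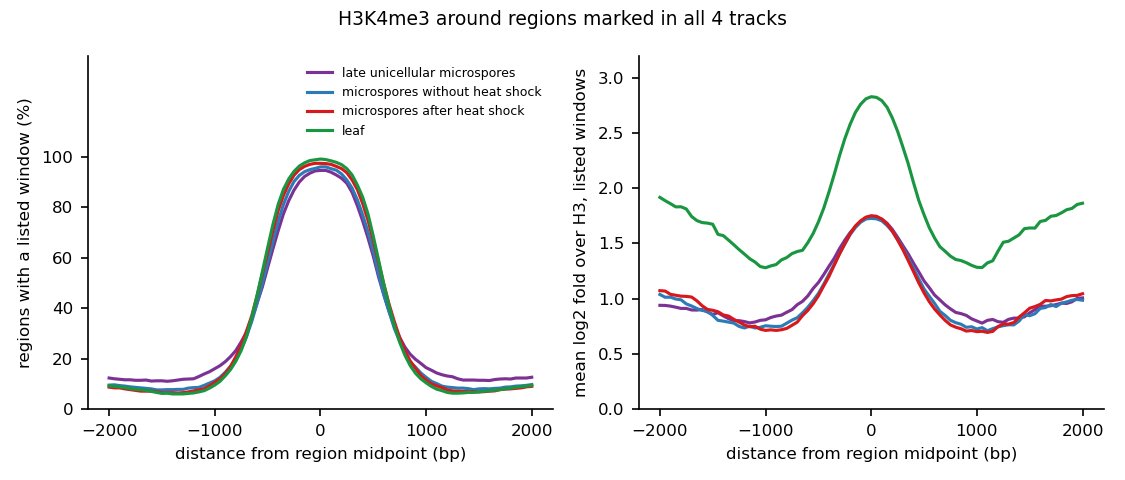
Profile of H3K4me3 around the midpoints of the 10075 regions marked in all 4 tracks. The left panel gives the percent of regions with a listed window at each distance in bp, and the right panel the mean log2 fold over H3 of those windows, with a line per track. At the midpoint the mean was 2.83 in leaf, 1.74 in late unicellular microspores, 1.73 without heat shock and 1.75 after heat shock.

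Microspore domains were compared with those of the other stages. Of the domains after heat shock, 78.7% overlapped a domain without heat shock, 70.1% a domain of late unicellular microspores and 78.8% a domain of leaf. Of the domains without heat shock, 66.7% overlapped a late domain. Of the late domains, 66.3% overlapped a leaf domain, 60.3% a domain after heat shock and 59.6% a domain without it. At a domain threshold of log2 2, 45% of domains after and 43.2% without heat shock overlapped late domains. Merged over the tracks, the domains gave 31619 regions with a median length of 750 bp. Of these, 19650 were marked in late unicellular microspores, 17605 without heat shock, 16850 after heat shock and 20553 in leaf. With thresholds set for equal numbers of marked windows in every track, the numbers were 18453, 17605, 16719 and 15646. Leaf then had the fewest marked regions in place of the most. All 4 tracks marked 10075 regions, 31.9%, with a median length of 1150 bp. Leaf alone marked 4478 regions with a mean leaf level of 2.08, and the 3 microspore tracks without leaf marked 983. Microspores after and without heat shock, but neither late unicellular microspores nor leaf, shared 888 regions, and 1807 further regions were marked in both and in leaf but not in late unicellular microspores. Late unicellular microspores and leaf shared 1225 regions that neither of the other tracks marked. With equal numbers of marked windows in every track these were 757, and those shared by heat shock and no heat shock alone were 1437, which turns the order of these classes.

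Regions marked in a single track were often short. Late unicellular microspores alone marked 4834 regions with a median of 300 bp, of which 464 were 600 bp or longer. The corresponding numbers were 1952 and 101 without heat shock, 1245 and 78 after heat shock, and 4478 and 2337 in leaf. With the mark threshold set so that every track has 229149 marked windows, leaf alone marked 2432 regions and the 3 microspore tracks without leaf 1925.

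**Figure D2:**
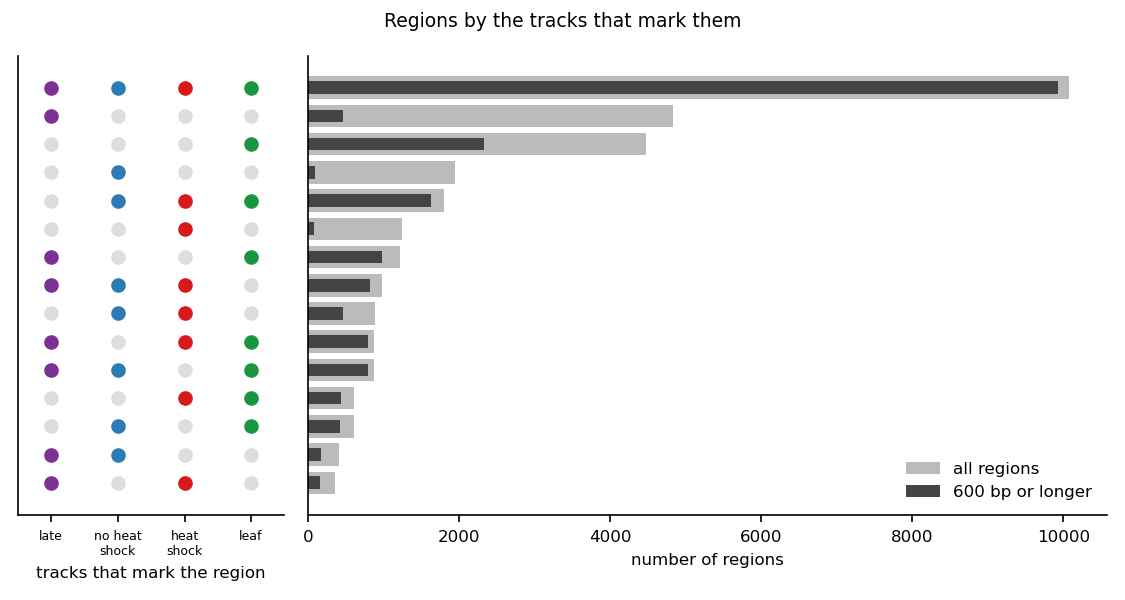
Numbers of regions by the tracks that mark them. Coloured dots name the tracks, grey bars count all regions and dark bars those of 600 bp or longer. The 10075 regions marked in all 4 tracks are mostly long, and the 4834 marked in late unicellular microspores alone are mostly short.

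Some regions of 600 bp or longer had no listed window at all in the other tracks. They numbered 578 for leaf alone, 442 for the 3 microspore tracks, 175 for late unicellular microspores alone, 128 for heat shock, no heat shock and leaf, 81 for late unicellular microspores and leaf, and 49 for heat shock and no heat shock. The examples here were chosen after their values were seen, among those with the highest levels in the tracks concerned. On chromosome 9 from 14703801 to 14704650 the late level was 4.41, with 2.61 without and 2.62 after heat shock. On chromosome 4 from 3765301 to 3767050 the levels were 2.46, 2.38 and 2.35. Shared by heat shock and no heat shock alone, the region on chromosome 2 from 4772801 to 4773450 had levels of 1.74 and 1.69 over 13 windows each. The leaf region on chromosome 5 from 29095751 to 29096900 reached 3.62 over 23 windows. Only 10 such regions belonged to heat shock alone and 24 to no heat shock alone.

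The effect of heat shock was addressed by comparing microspores after with microspores without it, and of the 4 contrasts it had the fewest regions past the threshold. Of 18263 regions, 287 were higher and 364 lower by 2-fold or more, 3.56% in all, and 14556, 79.7%, differed by less than log2 0.58. The centred differences had an SD of 0.47. Among regions with 10 or more shared windows, the highest difference lay on chromosome 5 from 6561501 to 6562500, at log2 2.72 after and 0.76 without heat shock over 13 windows, a centred difference of 1.96. Next came the region on chromosome 5 from 1925951 to 1926900, at 2.15 and 0.33, and the region on chromosome 5 from 5041551 to 5042450, at 2.71 and 0.97. A further region on chromosome 9 from 58659301 to 58660300 had 2.67 and 0.98. The 10 named higher regions had differences of 1.52 to 1.96 and were all marked in leaf as well, 7 of them in late unicellular microspores. Of all 287 higher regions, 73.2% had at least 5 listed windows in leaf, against 86.7% of the regions compared, and their median leaf level was 1.86 against 2.14. Under the same limit the lowest difference lay on chromosome 1 from 29331501 to 29332350, at 1.19 after and 3.25 without heat shock, a difference of -2.06. On chromosome 1 from 3360101 to 3360650 the levels were 0.89 and 2.5, and leaf had no listed window there. On chromosome 10 from 13456201 to 13457200 they were 1.06 and 2.61 over 19 windows. The 10 named lower regions had differences down to -2.06, the tenth at -1.44, and 8 were marked in late unicellular microspores and 6 in leaf.

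By presence of the mark, 3097 regions were marked after but not without heat shock and 3852 without but not after. This order turned when 8 marked windows were required, at 2724 and 2374, and among regions of 600 bp or longer the numbers were 1477 and 1499. The count of 651 regions moved to 71 with 15 shared windows and to 2607 with unlisted windows at log2 of 0. In regions long enough to compare their outer left and outer right parts, differences of these parts correlated at r = 0.032 over 4797 regions, and of 268 regions past the threshold on the left, 8 were past it in the same direction on the right. For whole regions, simulated counting error of H3K4me3 fragments put 49 to 290 past the threshold, against the 651 observed. The simulation compared 17786 to 17962 regions. Error in H3 was not simulated, so counting error as a whole may be larger.

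**Figure D3:**
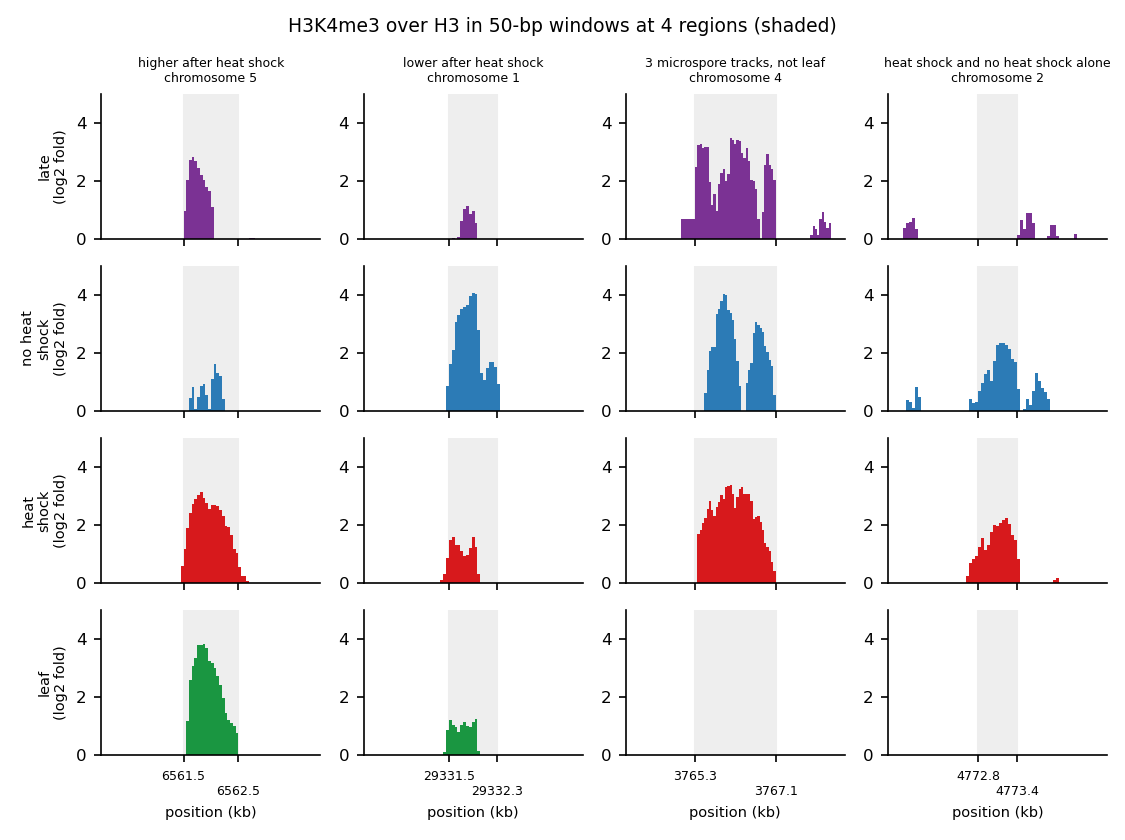
Log2 fold of H3K4me3 over H3 in 50-bp windows at 4 regions, shaded, with positions in kb and a row per track. From left to right they are the highest named region after against without heat shock, at 2.72 and 0.76, the lowest named region, at 1.19 and 3.25, a region of the 3 microspore tracks with no listed window in leaf, and a region of the heat shock and no heat shock tracks alone.

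The change from the starting stage was followed by comparing each of the other microspore tracks with late unicellular microspores. After heat shock, 1108 regions were higher and 1167 lower than in late unicellular microspores, 13.3% of 17095. Without heat shock, 1074 were higher and 1198 lower, 13.4% of 16904. Among regions with 10 or more shared windows, the region with the highest difference after heat shock, on chromosome 7 from 16029901 to 16031050, had 2.96 against 0.48 in late unicellular microspores, and leaf averaged 3.41 over its own listed windows there. Under the same limit the region with the highest difference without heat shock, on chromosome 2 from 7829801 to 7830850, had 2.99 against 0.53. A region on chromosome 7 from 26017051 to 26018200 was among the named higher regions of both contrasts, with centred differences of 1.90 after and 2.18 without heat shock. Likewise the lowest difference after heat shock lay on chromosome 3 from 14834151 to 14835200, at 1.06 against 3.84, a difference of -2.76. The region on chromosome 2 from 24962351 to 24963850 was lower in both contrasts, with differences of -2.64 after and -2.53 without heat shock, and leaf had no listed window there. Of the 10 named higher regions, 8 were marked in leaf after heat shock and 9 without.

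Many regions differed from late unicellular microspores with and without heat shock. Among 15823 regions measured in both contrasts, 480 were higher in both, 465 lower in both and 1 moved in opposite directions. Independent lists of these sizes would share 68.3 higher and 63.6 lower regions. The differences correlated at r = 0.766 across regions, which are not independent replicates, with a covariance of 0.333. Simulated tracks without any difference were compared with the same simulated late track, without error in H3. They gave 13 and 18 shared regions among 18410, and 0 in opposite directions. Their differences gave r = 0.572 and a covariance of 0.079. Opposite directions would need heat shock and no heat shock to differ by about log2 2, as 5 of 18263 regions did, so few could occur. As there is a single late track, part of the excess of shared regions may come from that track. The counts fell to 694 and 635 regions with 15 shared windows and rose to 7830 and 8241 with unlisted windows at log2 of 0. Outer left and right parts of regions correlated at r = 0.137 and 0.126, and of 641 and 553 regions past the threshold on the left, 83 and 68 were past it in the same direction on the right. For whole regions, simulated counting error of H3K4me3 fragments put 130 to 621 and 170 to 697 past the threshold, against the 2275 and 2272 observed. The simulation compared more regions, 20912 to 21047 and 19818 to 20007. It held no error in H3, so counting error as a whole may be larger.

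Of the 4 contrasts, late unicellular microspores against leaf had the most regions past the threshold. The late level lay below leaf by a median of -0.95 before centring. Relative to that shift, 2336 of 16710 regions were higher and 2202 lower, 27.2% in all, and without centring 363 were higher and 8006 lower, so that the share of higher regions fell from 51.5% to 4.3%. The count of 4538 moved to 1700 with 15 shared windows and to 13072, with 7785 higher and 5287 lower, with unlisted windows at log2 of 0. Among regions with 10 or more shared windows, the region with the highest difference, on chromosome 8 from 17611451 to 17612800, had 3.06 in late unicellular microspores and 0.41 in leaf over shared windows, and the other tracks averaged 2.81 without and 2.08 after heat shock over their own listed windows there. On chromosome 9 from 52909201 to 52910200 the late level was 4.59 and the leaf level 2.16. Under the same limit the region with the lowest difference, on chromosome 10 from 21552251 to 21553550, had 0.40 in late unicellular microspores and 4.75 in leaf. This region was also among those higher after heat shock than in late unicellular microspores, at 2.38 against 0.40. On chromosome 3 from 25259701 to 25261300 the levels were 0.82 and 4.83. Of the 10 named regions above leaf, 8 were marked without and 10 after heat shock, and of the 10 below it, 7 and 8 were. Outer left and right parts correlated at r = 0.127, and of 1208 regions past the threshold on the left, 235 were past it in the same direction on the right. For whole regions, simulated counting error of H3K4me3 fragments put 224 to 758 past the threshold, against the 4538 observed. The simulation compared more regions, 23845 to 23991, and held no error in H3, so counting error as a whole may be larger. The leaf track holds 1 H3K4me3 library and the late track 2.

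**Figure D4:**
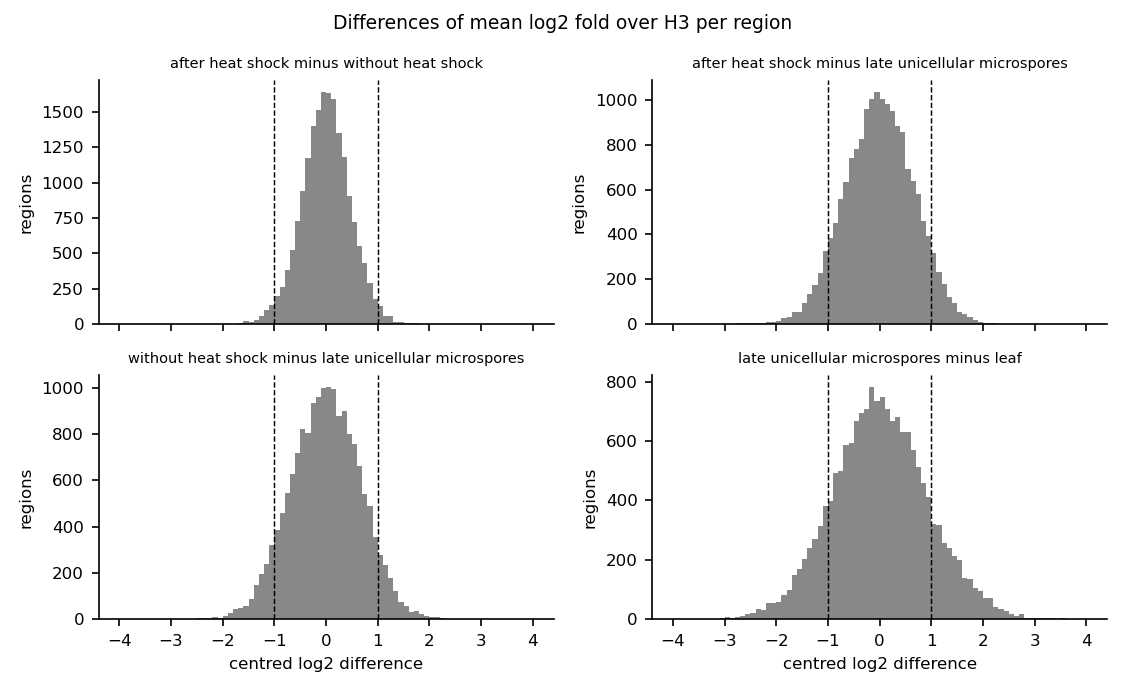
Centred log2 differences of the mean fold over H3 per region, in bins of 0.1, for the 4 contrasts, with dashed lines at the 2-fold threshold of 1 and -1. The SD was 0.47 for heat shock against no heat shock, 0.67 for each of these against late unicellular microspores and 0.92 for late unicellular microspores against leaf.

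Mean levels of regions correlated most between microspores after and without heat shock. Across regions, Pearson's r was 0.487 for that pair, 0.133 for late unicellular microspores with no heat shock, 0.121 with heat shock and 0.033 with leaf. Leaf correlated at 0.031 with no heat shock and 0.005 with heat shock. Over single windows listed in both tracks the order differed: r was 0.590 for heat shock with no heat shock, 0.363 for leaf with heat shock, 0.352 for leaf with no heat shock, 0.336 and 0.333 for late unicellular microspores with heat shock and no heat shock, and 0.301 for late unicellular microspores with leaf. Neither regions nor windows are independent replicates. Simulated H3K4me3 fragments without any difference, and without error in H3, gave r across regions of 0.576 to 0.707 for heat shock with no heat shock. For late unicellular microspores they gave 0.531 to 0.667 with no heat shock, 0.579 to 0.712 with heat shock and 0.723 to 0.816 with leaf.

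The marked regions were uneven along the chromosomes. Bins of 1 Mb held a median of 27 regions marked in all 4 tracks and up to 88, and 66 of 369 bins held at most 5. The longest stretch of such bins lay on chromosome 9 from 20 to 41 Mb. It held 346 regions, of which late unicellular microspores marked 245, microspores without heat shock 81, microspores after heat shock 54 and leaf 47. On chromosome 5 from 15 to 26 Mb the late track marked 181 of 246 regions and leaf 8, and on chromosome 6 from 15 to 30 Mb the late track marked 160 of 231 and leaf 38. Regions of late unicellular microspores alone fell into such bins in 13.8% of cases, regions without heat shock alone in 8.76%, regions of heat shock alone in 7.63% and regions of leaf alone in 1.27%. The share of regions that differed between heat shock and no heat shock ran from 3.10% on chromosomes 7 and 10 to 4.07% on chromosome 8.

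**Figure D5:**
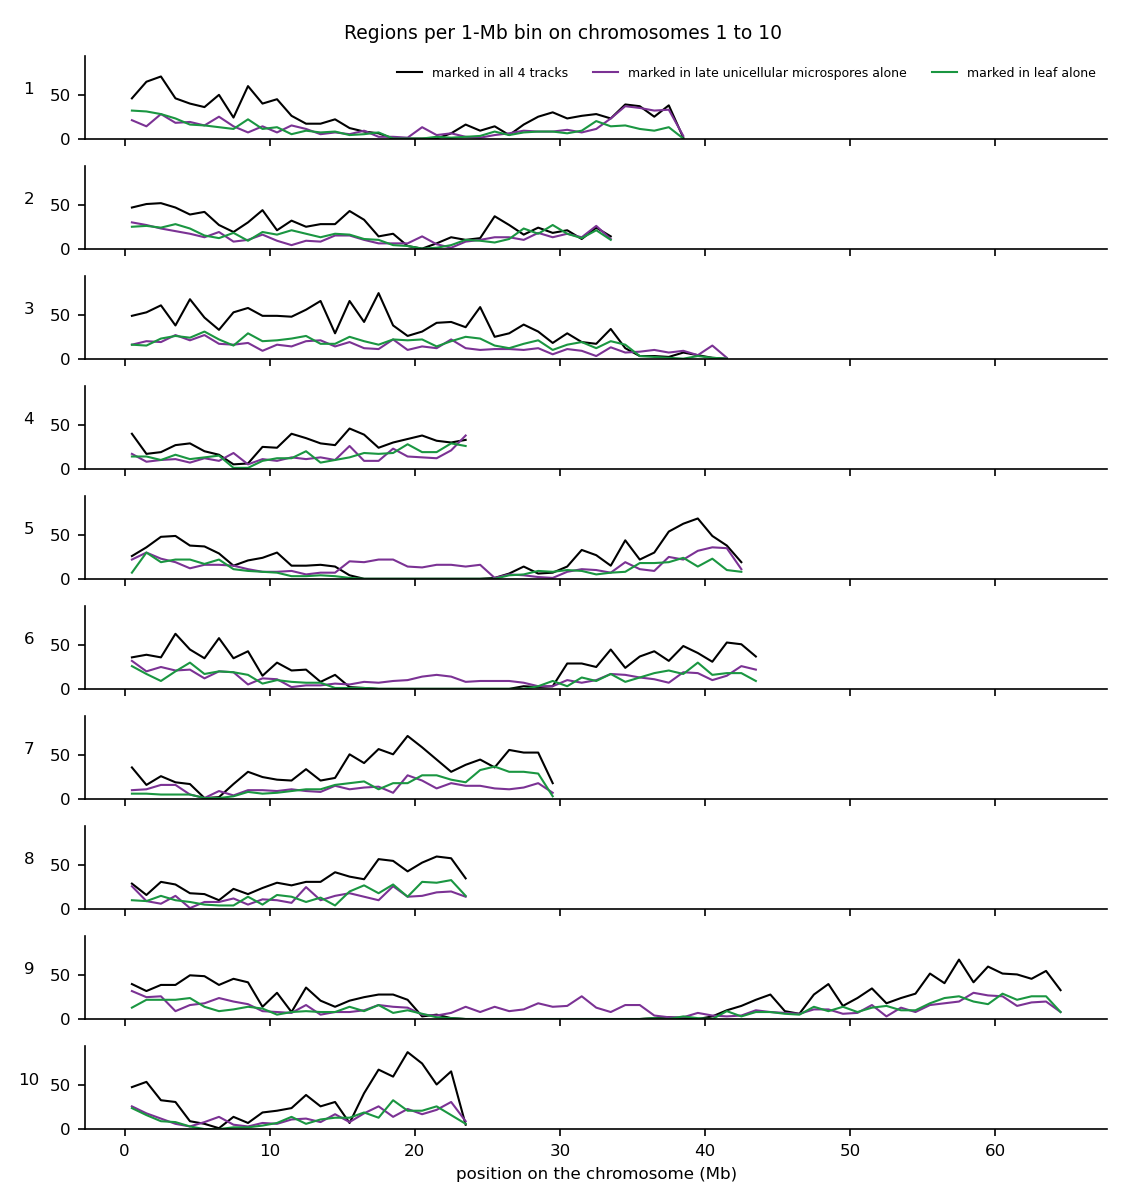
Regions per 1-Mb bin along chromosomes 1 to 10, with position in Mb, for regions marked in all 4 tracks, in late unicellular microspores alone and in leaf alone. On chromosome 9 between 20 and 41 Mb the regions of late unicellular microspores alone continue where the other lines lie near 0.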

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

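Among the regions measured against late unicellular microspores in both contrasts, 1 was past the 2-fold threshold in opposite directions. On chromosome 9 from 52328951 to 52329550, the level after heat shock was lower than in late unicellular microspores, at -1.93, and the level without heat shock was higher, at 1.03, a difference of -2.96 between the contrasts. These differences are over windows shared with the late track. Over each track's own listed windows, mean levels were 2.13 in late unicellular microspores, 2.61 without heat shock, 0.52 after heat shock and 0.73 in leaf, and on those levels the region without heat shock lies less than 2-fold above late unicellular microspores. The difference was not tested, since each track stands alone.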

How the results depend on the processing

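Of 163 alternative values for the counts and overlaps of the report, 103 stayed within the limits set and 60 moved, where a count moved if it changed by over 1.5 times. The 600-bp limit was chosen after seeing the data. Counts of regions past the threshold are given in the order heat shock against no heat shock, heat shock against late unicellular microspores, no heat shock against late, and late against leaf. With unlisted windows at log2 of 0 they were 2607, 7830, 8241 and 13072. With 15 shared windows they were 71, 694, 635 and 1700, and the shares of regions compared fell as well, from 3.56%, 13.3%, 13.4% and 27.2% to 0.76%, 8.69%, 8.56% and 20.4%; the cause was not tested. With 1 shared window the contrasts among microspores gave 1252, 3437 and 3586. A threshold of 0.58 gave 3707, 6670, 6571 and 8692, and of 2 gave 5, 53, 54 and 559. Odd windows alone gave 310, 1437 and 1404 and even windows 298, 1438 and 1442 for the contrasts among microspores. Of the 651 regions of heat shock against no heat shock, 257 were among the odd-window calls and 253 among the even. With the minimum of 5 shared windows kept, 14338 and 14411 of the 18263 regions could be compared there. How many of the 651 were among them was not counted. Without centring, late against leaf gave 8369. Quantile normalization, the lowess trend, the median over windows, the level filter, the span of 500 bp to each side of midpoints, regions outside mark-poor bins and regions of 600 bp or longer kept every such count within 1.5 times. Which of the higher and lower counts was larger changed with some setting in every contrast: a threshold of 0.58 gave 1859 and 1848 for heat shock against no heat shock, quantile normalization 1156 and 1118 for heat shock against late, a threshold of 2 gave 28 and 26 for no heat shock against late, and no centring 363 and 8006 for late against leaf.

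With a domain threshold of 2, domains numbered 7416 in late unicellular microspores, 6236 without and 5710 after heat shock, and 45% of domains after and 43.2% without heat shock overlapped late domains. With a mark threshold of 2, marked regions numbered 7055 in the late track, 6009 without and 5567 after heat shock. All 4 tracks then marked 1970, the 3 microspore tracks without leaf 142, heat shock with no heat shock 288, leaf alone 7353, late alone 1629, heat shock alone 397 and no heat shock alone 551. After but not without heat shock there were 1816, and the reverse 2258. With 8 marked windows the late track marked 13006, the 3 microspore tracks without leaf 644, late alone 2014, heat shock alone 778, no heat shock alone 827, and without but not after heat shock 2374. With equal numbers of marked windows, the 3 microspore tracks without leaf marked 1925, heat shock with no heat shock 1437, late with leaf 757 and leaf alone 2432. Among regions of 600 bp or longer, heat shock with no heat shock marked 466, leaf alone 2337, late alone 464, heat shock alone 78, no heat shock alone 101, after but not without 1477, and the reverse 1499. Higher thresholds and length limits lower the count of regions marked in a given track by construction. A class by tracks can rise, since a region that loses the mark in other tracks enters it. At a mark threshold of 2 leaf alone rose from 4478 to 7353, and late with leaf from 1225 to 1815. The cause of the other shifts was not tested.

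For the 80 named regions, some of them named in several contrasts, 944 of 971 alternative values moved by under 1 SD of their contrast's differences. A further 27 moved more and 0 changed sign. The named regions were chosen as the most extreme differences of the same tracks, so their kept signs are no support for the differences. Settings in which a named region was not measured gave no value. Of the 27, 20 came from leaving out centring, 6 from unlisted windows at log2 of 0 and 1 from the lowess trend. No paired analysis was possible because the replicates are pooled in the tracks, so replicates could not be left out or regrouped either. Settings listed before the data were examined on 500 bp around annotated starts and on whole gene bodies, and all for gene lists, were not run for lack of an annotation of this build. Depth is a further limit: at fold 2 the estimate, the least certain of the tracks, is 3.8 fragments in late unicellular microspores. Its effect at weak and strong levels was not compared.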

Other observations

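The test on short regions, the reading of the neighbour test and the choice of a second test for the heat shock contrast came after the results were seen. Regions that differed between heat shock and no heat shock had lower median levels in both other tracks, among regions with at least 5 listed windows there. The median leaf level was 1.86 for regions higher and 1.89 for regions lower after heat shock, against 2.14 over all regions measured, and the median late level was 1.08 and 1.14 against 1.29. Of the higher regions, 73.2% had at least 5 listed windows in leaf, and of the lower regions 71.7%, against 86.7% of all. A hypothesis that the higher regions are those strongly marked in leaf was tested against 10000 random lists matched on level. The median stood at percentile 0 of them. The hypothesis that the lower regions are those strongly marked in late unicellular microspores met percentile 0.1. Neither set thus had the higher levels predicted. The lists were not matched on region length or shared windows, and medians were low in both directions. A further link to leaf or late marking is therefore not settled.

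Regions marked in late unicellular microspores alone were weighed against scattered background fragments, which would fall into mark-poor bins about as often as elsewhere. Of the 4370 regions shorter than 600 bp, 14.4% lay in such bins (95% Wilson interval 13.4% to 15.5%), where such bins are 17.9% of all and over 8.95% was set as the mark of background. Background may therefore account for many short regions. Of the 464 longer regions, 7.54% did (5.47% to 10.3%), an interval that holds 8.95%, so background and a mark of that stage cannot be told apart for them. By estimate the late track also has the fewest fragments at a fold of 2, 3.8 against 4.1 without heat shock, though its value is the least certain. A stage difference stays open as untested.

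Regions that differed between heat shock and no heat shock were weighed against background, changes shared by neighbours and counting error alone. In mark-poor bins lay 1.69% of them (0.95% to 3.0%), against 0.84% of all 18263 regions compared; with so few compared regions there the 8.95% set for background could hardly be reached, the interval passes the 2% set against it, and background stays open. The first test of counting error asked whether the nearest region at 10 to 30 kb differed in the same direction, and 51.6% did, within the 45.9% to 54.1% of shuffles; this was the value predicted for counting error, but changes confined to single regions would give it too, so it was afterwards read only as a test of changes shared by neighbours, which it leaves open. A second test then compared the outer parts of long regions, and with the left part past the threshold the right part differed by a median of 0.06 in the same direction (-0.01 to 0.12), where 0.1 or less was set for counting error and over 0.3 against it, a level that the other contrasts, at 0.20 to 0.21, did not reach either. The second test thus met the value set for counting error, but changes confined to a part of a region would give it too. As no contrast reached 0.3, the test does not decide on the cause. Simulated counts gave 49 to 290 such regions against 651, with assumed fragment lengths and without error in H3. Counting error stays open, and an effect of heat shock stays open as untested.

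The low correlation of region means of the late track with the others was weighed against shallow windows and against the choice of regions. In the 7045 regions with 6 or more intervals per late window, r with no heat shock was 0.129, and 0.093 in the 3412 with more than 6. For shallow windows 0.3 or more was needed, and under 0.2 was set against them. The files do not define the interval number, and 6 lies close to the median of 5 over all listed late windows. The test therefore does not exclude shallow windows. Simulated H3K4me3 fragments of 150 to 300 bp, without any difference, gave r of 0.531 to 0.667 for this pair, against 0.133 observed. Those values argue against counting error of H3K4me3 fragments alone at the estimated depths. Error in H3 was not simulated, and the late depth is the least certain. In regions marked in all 4 tracks, r was 0.121 for this pair and 0.503 for heat shock with no heat shock, a difference of 0.382. This argues against the choice of regions as the source of the difference between these pairs. Those regions are also chosen by a threshold, so an effect of region choice on each r is not excluded. A difference between stages stays open as untested. The pattern is not particular to the late track, since region means of leaf correlated at 0.031 and 0.005 with no heat shock and heat shock, nor does it hold alike for single windows, where late with no heat shock gave 0.333.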
